A study of Homo sapiens with 31 samples.

How the data were processed

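The data are bulk RNA sequencing of 31 libraries from cells sorted on an Aria II instrument straight into Trizol, with libraries made by Illumina's standard protocol from total RNA, per the labels' protocols. The submitters' processing notes name FastQC for read quality, STAR for alignment to GRCh38 and edgeR. The program that counted reads per gene, the annotation release, the strandedness of the libraries and any filter are not stated. The deposited table of counts holds whole numbers per gene that are not normalized, 1 column per library, and was the input to every test. The deposited CPM table divides those counts by each library's total, without scaling factors; CPM recomputed from the counts differed from it by at most 0.005. All columns were matched to sample titles by name. The table has 45663 genes, each with an identifier, symbol and biotype, plus the reporter (Venus); 42111 identifiers (92.2%) are in GENCODE 29, from which gene positions on GRCh38 were taken. No 2 replicates of a group were identical or nearly so: over 26 pairs the lowest chi-square per degree of freedom was 7.393, on genes with at least 20 counts in the pair.

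Groups are genotype, sorted fraction and day, from the sample titles. In 1 library, MYB+/- YFP- day 12 replicate 2, the description carries the number 3. The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) with robust estimation, TMM scaling and edgeR's own filter on low counts, which left 23004 genes, in a model with 1 mean per group over all 31 libraries. Groups hold 2 or 3 libraries, so all 12 share 1 estimate of the spread (19 residual degrees of freedom, biological coefficient of variation 38.9%). Adjusted p is Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Log2 differences are edgeR's, with standard errors from the same fit, and where a group was at 0 in all libraries the fold was bounded with a floor of 3 counts over the group. Of the 20 comparisons, 4 set MYB-/- against MYB+/-, 6 set the sorted fractions against each other, 3 set day 12 against day 6, 4 set a modified line against MYB+/+, and 3 are interactions.

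A set of 27 gene lists was written before the data were examined: embryonic and fetal globins, adult globins, erythroid, heme synthesis, megakaryocyte, granulocyte, macrophage, mast cell and eosinophil, lymphoid, class II antigen presentation, endothelial, hemogenic progenitor, Notch and arterial, mesenchyme, pluripotency, cardiac, endoderm and liver, S phase, G2 and M phase, MYB targets described in other blood cells, the MYB family, MYB cofactors, HOXA genes, p53 and apoptosis, cytokine receptors, immediate early and stress genes, and hypoxia and glycolysis. Each was tested in each comparison with camera (limma 3.58.1), which sets a list's genes against all others, with a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 27 lists of a comparison. Members called are counted over all genes tested and again adjusted over the list alone. Lists share some genes, and several hold genes that more than 1 blood lineage uses.

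The rule for genes named in the text was also fixed before the data were examined. It allows MYB, up to 8 genes each way with the largest log2 difference among those called, at 10 CPM or more in the higher group and, between 2 groups, without overlap of libraries, and of each list the first 5 genes and the 2 called members with the largest change each way; lists of 8 genes or fewer may be named in full. Non-coding and clone names, XIST and Y-linked genes were left out. The values of 1 gene that the rule allows are not reported here.

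Replicate numbers in the titles were checked for pairing by correlating, across 11810 genes, the deviations of libraries from their group means. Numbers were taken to pair samples where at least 3 pairs each had a correlation over 0.1. They pair the fractions of MYB-/- at day 12 (0.18, 0.44 and 0.4 for the 3 numbers) and of MYB+/+ at day 6 (0.35, 0.35 and 0.26), where the block gave 10705 and 8268 genes. The other comparisons hold fewer pairs, or a pair at or under 0.1, and were not treated as paired. GC content was that of each gene's longest GENCODE 29 transcript, known for 22755 of the tested genes (98.9%), and each library's GC slope was fitted on 8231 protein-coding genes with a mean log2 CPM above 4.

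Alternatives written before the data were examined were DESeq2 1.42.0, median-ratio size factors, no filter on low counts, a test against a 2-fold change, fits with only the groups compared or only the 19 libraries of the modified lines, the replicate block, and leaving out each library in turn. Leaving 1 library in a group assumes that it varies like the other groups. Added after seeing the data were the GC slope as a covariate, fits without the 6 MYB+/+ day 12 libraries, and crossed replicate numbers at day 6. The test was tried on simulated counts with the spreads and library sizes of the real libraries and 50 genes changed at each of 4 sizes. Each gene had its mean over all 31 libraries in every group, apart from the changes made. Changed genes were drawn above a minimum level, and the GC trend at day 6 was left out. The shares recovered therefore do not cover low genes or genes found in only some groups. For MYB-/- against MYB+/- YFP+ cells at day 12 (21557 genes) it recovered 2% of 1.5-fold, 16% of 2-fold, 72% of 4-fold and 94% of 8-fold changes with 12 false calls of 104; at day 6 (21422 genes) 0%, 2%, 56% and 82% with 4 false calls of 74; and for the interaction of genotype with day (21492 genes) 0%, 0%, 24% and 64% with 0 false calls of 44. The fit with the GC slope was tested in the same way for the day 6 genotype comparisons, on simulated counts that carry each library's slope, a check added after seeing the data. It recovered 10% of 2-fold, 82% of 4-fold and 100% of 8-fold changes in YFP+ cells (21580 genes, 4 false calls of 100), and 18%, 72% and 90% in YFP- cells (21543 genes, 9 false calls of 100). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.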

Results

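RNA was sequenced from blood-forming cultures grown out of human embryonic stem cells, in which BMP4 and VEGF induced mesoderm and neither serum nor blood cytokines were added. The study asks what the transcription factor MYB, which maintains blood progenitors, does in the first wave of human blood formation. In the modified lines a cassette with a yellow fluorescent reporter (Venus) sits in 1 allele of MYB (MYB+/-) or in both (MYB-/-), placed there with TALENs, which are programmable nucleases. Cells of these lines were sorted at day 6 and day 12 into reporter-positive (YFP+) and reporter-negative (YFP-) fractions. Cells of the MYB+/+ line were sorted into CD43+ and CD43- fractions, CD43 being the early blood-cell surface protein encoded by SPN. The series text names CD34 where the sample titles name CD43. The 31 libraries, described as biological repeats, form 12 groups. At day 6 each fraction has 2 MYB-/- and 2 MYB+/- libraries, and at day 12 it has 3, except for 2 in MYB+/- YFP-. Each MYB+/+ group has 3. The number of clones behind each modified genotype is not given, so a difference between genotypes is also a difference between lines. Library totals ranged from 6869555 to 10512515 counts in the 6 MYB+/+ day 12 libraries and from 17872697 to 30175855 counts in the other 25. Levels are CPM (counts-per-million) over each library's total for the tested genes, scaled by its TMM factor, and so differ from the deposited CPM. They are given as mean ± SD over the libraries of a group, and intervals and floors from counts cover counting error only.

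MYB was the first gene examined, because its counts bear on the genotype labels. MYB (ENSG00000118513.18, a protein-coding gene at 135181315 to 135219173 on chromosome 6 of GRCh38) stood at 15.5 ± 3.76 CPM in MYB-/- YFP+ cells at day 12. It stood at 141 ± 71.1 CPM in MYB+/- YFP+ and 117 ± 38.1 CPM in MYB+/+ CD43+ cells (n = 3 each). At day 6 the corresponding levels were 165 ± 70.5 CPM (n = 2), 192 ± 78.4 CPM (n = 2) and 226 ± 20 CPM (n = 3). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment MYB fell by 3.19 on the log2 scale in MYB-/- against MYB+/- YFP+ cells at day 12 (SE 0.49, adjusted p = 0.000215). It was not called between the same groups at day 6 (-0.22, SE 0.56, adjusted p = 1). The position of the cassette within MYB is not given in the sources used, so counts left in MYB-/- cells neither check nor contradict that label. Venus, the reporter's own transcript, stood at 1460 ± 606 CPM in MYB-/- and 427 ± 191 CPM in MYB+/- YFP+ cells at day 6. At day 12 the levels were 89 ± 33.2 and 143 ± 53.2 CPM, and neither difference was called (adjusted p = 1 and 0.431). In YFP- cells Venus stood at 13.5 ± 0.0202 CPM in MYB-/- and 36.6 ± 14.2 CPM in MYB+/- at day 6. At day 12 it stood at 1.36 ± 0.921 and 7.16 ± 3.68 CPM and was called lower in MYB-/- cells (-2.39, adjusted p = 0.00246), a call lost without MYB+/- YFP- replicate 2 (adjusted p = 0.0787).

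**Figure D1:**
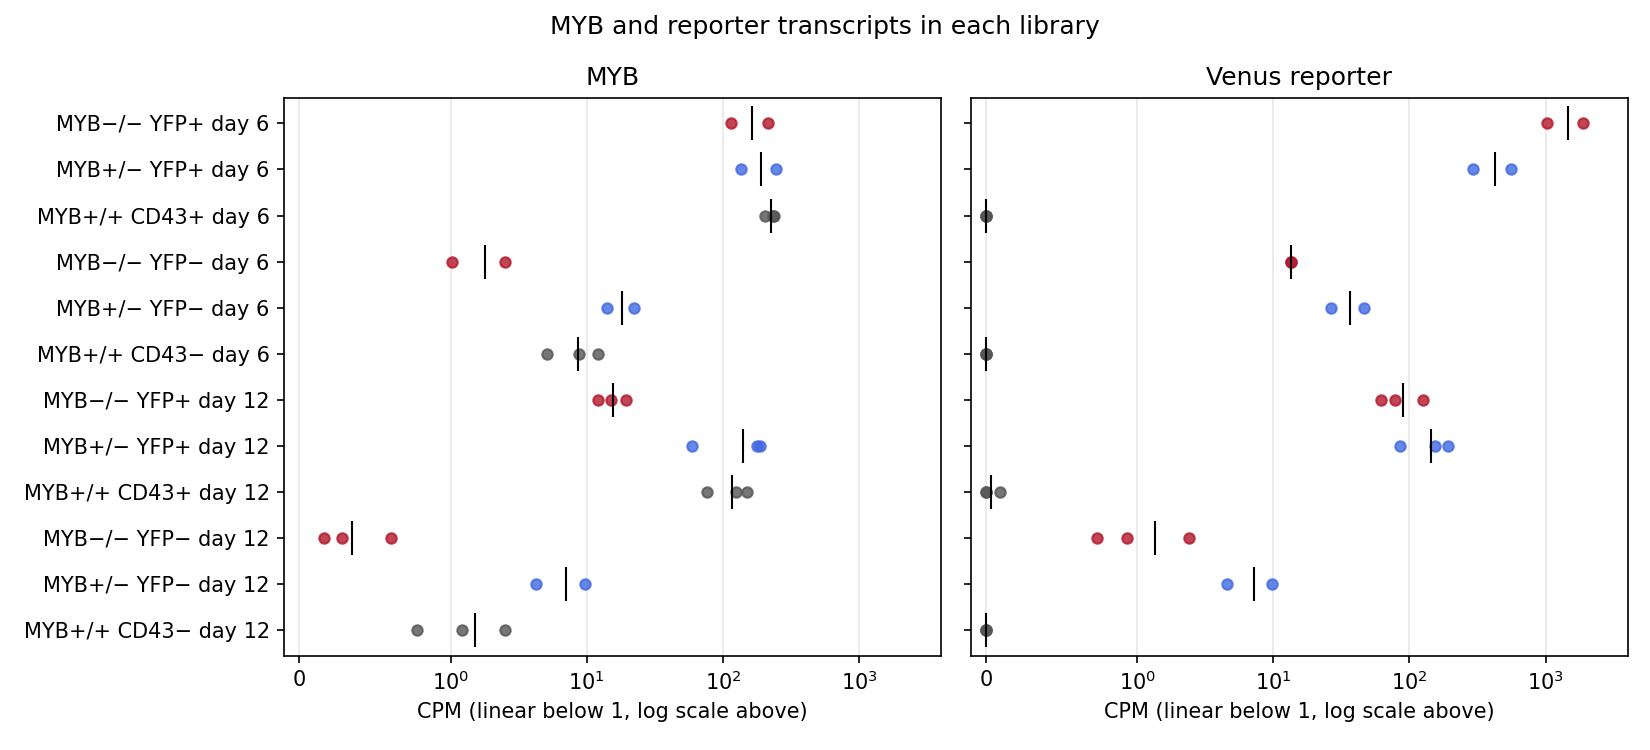
MYB and Venus CPM in each of the 31 libraries, by group. Points are libraries, black ticks are group means, colours mark genotype, and the axis is linear below 1 CPM and logarithmic above. MYB in MYB-/- YFP+ cells at day 12 averages 15.5 CPM against 141 CPM in MYB+/- YFP+ cells.

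The comparison of MYB-/- with MYB+/- YFP+ cells at day 12 asks what loss of MYB changes in cells that have switched on the MYB locus, and the largest differences lay in granulocyte genes. MPO, which encodes the peroxidase of neutrophil granules, stood at 2.82 ± 3.22 CPM in MYB-/- cells and at 11600 ± 4860 CPM in MYB+/- cells (n = 3 each). The granule protease gene PRTN3 and its neighbour AZU1, which encodes an antimicrobial granule protein, fell with it. GFI1, a repressor required for neutrophil development, stood at 0.457 ± 0.288 against 44.6 ± 15.3 CPM, and CEBPE, a regulator of late granulocyte maturation, at 2.05 ± 2 against 137 ± 89.1 CPM. Genes of eosinophils and mast cells fell too, among them EPX, the eosinophil peroxidase, at 0.517 ± 0.237 against 933 ± 722 CPM, and HDC, the enzyme that makes histamine. EdgeR's test called 1339 of 23004 genes, 429 higher and 910 lower in MYB-/- cells. The share of called genes that were higher was 32%, and 41.9% with the median-ratio factors. Of all genes 228 passed a test against a 2-fold change. The log2 differences were -12 for MPO (SE 1.7, adjusted p = 6.03e-05), -12.2 for PRTN3 (SE 1.5, adjusted p = 1.36e-05), and -8.58 for AZU1 (SE 0.84, adjusted p = 6.93e-07). They were -6.56 for GFI1 (SE 0.5, adjusted p = 2.06e-08), -10.8 for EPX (SE 0.98, adjusted p = 4.38e-07) and -5.53 for HDC (adjusted p = 8.82e-06). MPO and EPX lie near each other on chromosome 17 (MPO from 58269856 to 58280935, EPX from 58192737 to 58205174). PRTN3 and AZU1 lie on chromosome 19 (PRTN3 from 840960 to 848175, AZU1 from 825097 to 832018), and GFI1 lies on chromosome 1 (92474762 to 92486876). Of the granulocyte list, 19 of 20 measured members fell and 19 fell adjusted over the list alone (median log2 difference -6.09, camera adjusted p = 4.9e-34, adjusted p = 0.0055 with an estimated correlation). In the mast cell and eosinophil list 11 of 14 fell, and 11 adjusted over the list alone (median -5.44, camera adjusted p = 4.2e-16, 0.0055 with an estimated correlation). The number of genes called was 579 without MYB-/- replicate 1, 407 without MYB-/- replicate 2, 416 without MYB+/- replicate 2 and 2592 without MYB+/- replicate 1. Of the granulocyte list, 12 to 19 members fell under every setting and omission tried. With the 6 libraries compared alone in the fit 143 genes were called, and with each library's GC slope in the model 3176.

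Megakaryocyte and endothelial genes lay higher in the same MYB-/- YFP+ cells at day 12, with less certainty. TREML1, which encodes a receptor stored in platelet granules, stood at 195 ± 39.5 CPM in MYB-/- and 34.1 ± 20.2 CPM in MYB+/- cells. KDR, the main VEGF receptor of endothelium and of early blood precursors, stood at 1270 ± 245 against 271 ± 160 CPM, and TEK, the angiopoietin receptor, at 150 ± 25.9 against 34.7 ± 20 CPM. ITGA2B and PF4, which encode the platelet integrin CD41 and platelet factor 4, were not called. MYB+/- replicate 1 held 4810 and 2830 CPM of them, close to MYB-/- cells, and the other MYB+/- libraries at most 1440 and 778 CPM. TREML1 rose by 2.52 (SE 0.53, adjusted p = 0.00534), KDR by 2.23 (SE 0.44, adjusted p = 0.00252) and TEK by 2.12 (SE 0.4, adjusted p = 0.00213). ITGA2B differed by 1 (SE 0.59, adjusted p = 0.365) and by 2.08 without MYB+/- replicate 1 (adjusted p = 0.0294). PF4 differed by 1.59 (adjusted p = 0.202) and by 2.64 without it (adjusted p = 0.0283). Among 19 megakaryocyte list members 4 rose, and 12 adjusted over the list alone (median 1.59, camera adjusted p = 1e-09, but adjusted p = 0.29 with an estimated correlation). Leaving out MYB+/- replicate 1 gave 12 called members, and leaving out MYB-/- replicate 1 or 2 or MYB+/- replicate 2 or 3 gave 1. The endothelial list of 24 had 3 higher members, 3 adjusted over the list alone (median 1.04, camera adjusted p = 6.9e-07, 0.47 with an estimated correlation). MYB+/- replicate 3 lay at a median of 6.24 log2 CPM for this list, near the MYB-/- libraries (6.32 to 6.99). MYB+/- replicates 1 and 2 lay at 3.66 and 4.16. Of 15 members of the Notch and arterial list 3 were higher, 3 adjusted over the list alone (median 0.83, camera adjusted p = 0.00092, 0.52 with an estimated correlation). HES1, a direct Notch target, rose by 1.68 (adjusted p = 0.0108), a call that ended without MYB-/- replicate 1 (adjusted p = 0.0565) or MYB+/- replicate 2 (adjusted p = 0.0609). Other genes that rose were THRB, a thyroid hormone receptor, by 2.69 (adjusted p = 0.00111), and ANK3, a membrane anchor protein, by 2.63 (adjusted p = 0.000791). With the 6 libraries compared alone in the fit the calls of KDR (adjusted p = 0.106), TEK (0.0937), THRB (0.0639) and ANK3 (0.0757) ended.

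**Figure D2:**
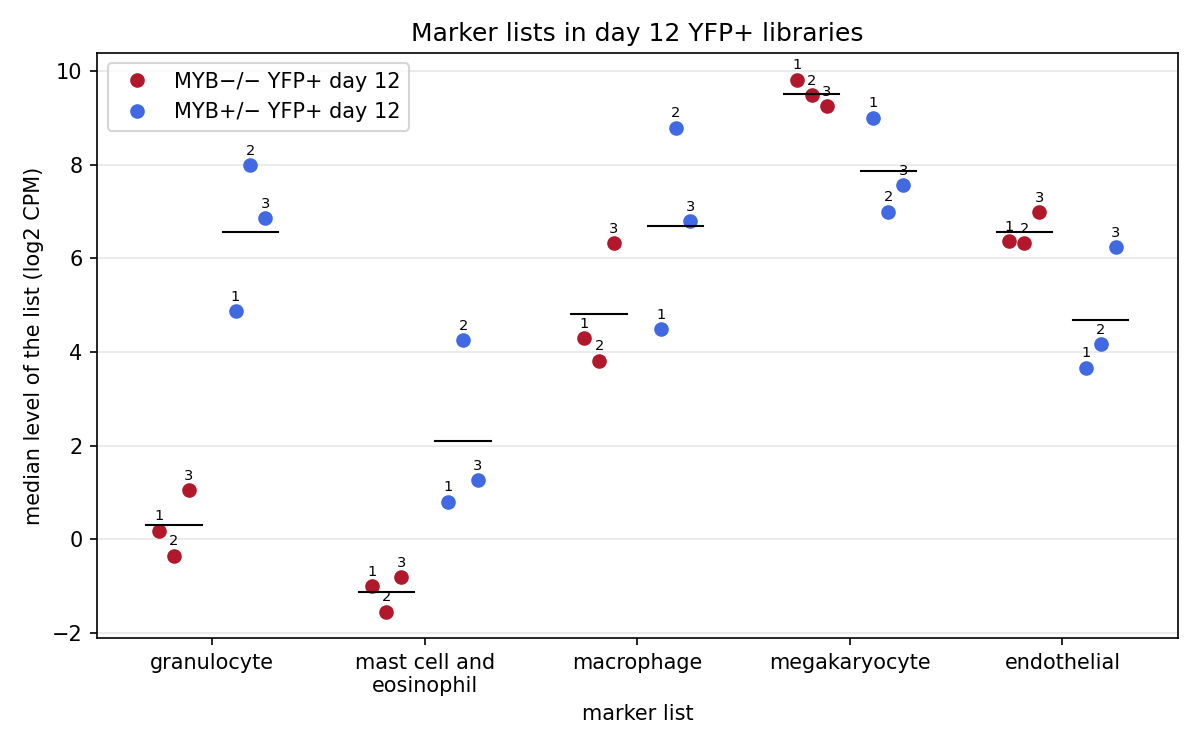
Median log2 CPM of the granulocyte, mast cell and eosinophil, macrophage, megakaryocyte and endothelial lists in each day 12 YFP+ library of MYB-/- (red) and MYB+/- (blue) cells. Numbers are replicates and lines are group means. MYB+/- replicate 1 lies at 9.01 for the megakaryocyte list, near the MYB-/- libraries (9.25 to 9.82), and at 4.87 for the granulocyte list, where the MYB-/- libraries lie between -0.36 and 1.05.

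Genes named in the literature as MYB targets fell as a group in MYB-/- YFP+ cells at day 12. BCL2, which protects cells from apoptosis, fell by 4.44 on the log2 scale (adjusted p = 2.23e-05). Further genes that fell are named here without regard to that list. ALAS1, of the heme synthesis list, makes the first intermediate of heme in all cells. It stood at 45.3 ± 9.16 CPM against 512 ± 251 CPM in MYB+/- cells (-3.5, adjusted p = 8.92e-07). CSF3R, the receptor for the granulocyte growth factor G-CSF, fell by 3.00 (adjusted p = 0.000174) and IL2RG, the shared chain of several interleukin receptors, by 3.37 (adjusted p = 3.79e-05). Of 18 measured MYB targets 6 fell, and 6 adjusted over the list alone (median -0.65, camera adjusted p = 3.5e-07, 0.0081 with an estimated correlation). A further 4 lists passed camera with the preset correlation and lost the call with an estimated one. Of 23 erythroid genes 1 was higher, and 5 adjusted over the list alone (median 1.01, camera adjusted p = 0.00092, estimated 0.52). In the macrophage list of 23, 2 members were lower, and 4 adjusted over the list alone (median -1.35, camera adjusted p = 9.3e-05, estimated 0.52). In the S phase list of 26, 3 were lower, and 17 adjusted over the list alone (median -0.90, camera adjusted p = 2.3e-09, estimated 0.38). In the endoderm and liver list of 14, 4 were lower, and 7 adjusted over the list alone with 1 higher (median -1.29, camera adjusted p = 0.0051, estimated 0.52).

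The other 17 lists were not called by camera between MYB-/- and MYB+/- YFP+ cells at day 12. No member was called in the lists of embryonic and fetal globins (camera adjusted p = 0.15), adult globins (0.9), class II antigen presentation (0.076), G2 and M phase (0.059), HOXA genes (0.43), p53 and apoptosis genes (0.25) and immediate early genes (0.45). Adjusted over the list alone, 1 adult globin was higher and 2 class II genes were lower. Called members were 1 higher and 1 lower for heme synthesis (0.25) and 1 higher and 1 lower for lymphoid genes (0.45; 1 and 4 adjusted over the list alone). They were 3 higher and 4 lower for hemogenic progenitor genes (0.25), and 1 lower for mesenchyme (0.3; 0 adjusted over the list alone). Pluripotency genes had 3 higher and 1 lower (0.56; 4 and 2 adjusted over the list alone; the median was -0.54 and camera's direction up). Cardiac genes had 1 lower (0.33), the MYB family 1 lower (0.13) and MYB cofactors 2 lower (0.33). Cytokine receptors had 1 lower (0.25; 2 higher and 3 lower adjusted over the list alone), and hypoxia and glycolysis genes 1 higher and 2 lower (0.43). RUNX1, a master regulator of blood stem cell formation, differed by -0.72 (SE 0.48, adjusted p = 0.441) and was not called.

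At day 6 few differences between MYB-/- and MYB+/- YFP+ cells passed the test. The gene that differed most clearly was ST8SIA1 (chromosome 12, 22063773 to 22437041), which encodes the synthase of the ganglioside GD3, at 1.35 ± 0.765 CPM in MYB-/- and 17.5 ± 0.395 CPM in MYB+/- cells (n = 2 each). Embryonic globin HBE1, at 6880 ± 1030 and 8310 ± 2730 CPM, was abundant in both, and GFI1 stood at 188 ± 74.8 and 244 ± 43.4 CPM. MPO, at 0.0881 ± 0.00949 and 0.362 ± 0.0544 CPM, was hardly detected at this day. Of 23004 genes 421 had an unadjusted p under 0.05 in edgeR's test, a share below the 0.05 that tests without any difference would give. Lower in MYB-/- cells by edgeR's test were 2 genes, with none higher, and DESeq2 called 7. The 2 genes were ST8SIA1 (-3.70, SE 0.53, adjusted p = 0.004) and GAS8, a cilium gene below 10 CPM that was named only after its values were seen (-3.81, adjusted p = 0.004). With the 4 libraries alone in the fit 0 genes were called. ST8SIA1's call ended without MYB-/- replicate 1 (adjusted p = 0.336), and that of GAS8 without MYB-/- replicate 1 or 2 or MYB+/- replicate 1 (adjusted p = 0.269, 0.822 and 0.0713). Medians were higher in MYB-/- cells for the endothelial list (0.77, camera adjusted p = 2.3e-08, 0.63 with an estimated correlation) and for the Notch and arterial list (1.02, camera adjusted p = 4.9e-09, estimated 0.31). No member was called in either, 0 adjusted over the list alone. The granulocyte list was not called (median -0.11, camera adjusted p = 0.66). Its first genes were low in MYB-/- and MYB+/- cells at this day. ELANE stood at 0.0474 and 0.0286 CPM, PRTN3 at 0.0948 and 0.11, CEBPE at 0.654 and 0.526 and AZU1 at 4.39 and 3.72 CPM. For genes this low the test could hardly show a difference. With 2 libraries a side the simulated test recovered 2% of 2-fold and 56% of 4-fold changes. The 2 day 6 replicates of each of these groups differed from each other by transcript GC content, with a Spearman correlation across 8231 genes, which are not independent replicates, between 0.88 and 0.9.

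YFP- cells at day 6 were sorted for low reporter signal, and here blood and endothelial precursor genes lay lower in MYB-/- cells as groups, although edgeR's test called no single gene. RUNX1 stood at 8.98 ± 0.337 CPM in MYB-/- and 50.4 ± 24.9 CPM in MYB+/- cells (n = 2 each). GFI1B, a repressor required for red cell and platelet development, stood at 0.43 ± 0.0194 and 4.12 ± 2.77 CPM. KDR stood at 821 ± 172 and 2060 ± 276 CPM, and HBE1 at 16.9 ± 3.69 and 230 ± 174 CPM. By edgeR's test 0 genes differed, and 488 of 23004 genes had an unadjusted p under 0.05, again a smaller share than 0.05. DESeq2 called 16, among them GFI1 (adjusted p = 1.69e-05), MYB (0.000309), GFI1B (0.0245) and RUNX1 (0.0482). GFI1 came close to the threshold (-3.14, SE 0.52, adjusted p = 0.0606) and was called without MYB+/- replicate 2 (-3.73, adjusted p = 0.00293), the single gene called in that fit. GFI1 was also called in 7 of the 11 alternative settings. Planned ones among them were DESeq2, no filter on low counts and the replicate block. The GC slope, the crossed numbers and the fit without the 6 MYB+/+ day 12 libraries were added after seeing the data. MYB differed by -3.32 (SE 0.63, adjusted p = 0.155 in edgeR's test). Venus, at 13.5 ± 0.0202 and 36.6 ± 14.2 CPM without overlap, was not called (-1.43, SE 0.55, adjusted p = 1), but it lay lower in MYB-/- cells with these genes. For the blood genes, which were higher in YFP+ cells, this comparison therefore does not separate expression within YFP- cells from a different share of YFP+ cells in the gate. KDR in MYB+/- cells stood at 1080 ± 307 CPM in YFP+ cells, below its YFP- level, but edgeR's test did not call that difference (-0.94, adjusted p = 0.281). YFP+ cells at this mean level would not bring the gate to 2060 CPM. Those that fall in the gate may differ from that mean, so for KDR the question stays open too. The hemogenic progenitor list was lower (26 genes, median -1.52, camera adjusted p = 1.8e-33, 2.8e-05 with an estimated correlation) with 14 members lower adjusted over the list alone. The endothelial list was lower as well (24 genes, median -1.53, camera adjusted p = 4.8e-27, estimated 0.02, 1 adjusted over the list alone), and in MYB+/- cells its median was not higher in YFP+ than in YFP- cells (-0.65, camera adjusted p = 0.16). The erythroid list was also lower in MYB-/- cells (median -1.20, estimated 0.035, 4 adjusted over the list alone).

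YFP- cells at day 12 differed widely between the genotypes, with connective tissue genes higher and blood genes lower in MYB-/- cells. COL1A1, the main fibrillar collagen of bone and skin, stood at 30400 ± 10200 CPM in MYB-/- (n = 3) and 2650 ± 370 CPM in MYB+/- cells (n = 2), and GAS1, a hedgehog co-receptor, at 201 ± 63.4 and 10.5 ± 1.13 CPM. ITGA2B, the platelet integrin, stood at 341 ± 221 against 3300 ± 996 CPM, and CSF1R, the macrophage growth factor receptor, at 19.4 ± 14.7 against 852 ± 68 CPM. SPN, which encodes CD43, stood at 17.1 ± 11.5 against 223 ± 67.5 CPM. There 5159 genes differed by edgeR's test, 2450 higher and 2709 lower in MYB-/- cells. Log2 differences were 3.52 for COL1A1 (adjusted p = 0.0021), 4.25 for GAS1 (SE 0.6, adjusted p = 2.54e-05), -3.28 for ITGA2B (SE 0.66, adjusted p = 0.000846) and -5.46 for CSF1R (SE 0.87, adjusted p = 9.25e-05). They were -3.70 for SPN (adjusted p = 4.28e-05) and -5.00 for SPI1, the master regulator of macrophages and granulocytes (adjusted p = 7.66e-05). Of 24 mesenchyme genes 23 were higher, and 24 adjusted over the list alone (median 3.21, camera adjusted p = 1.3e-18, 0.015 with an estimated correlation). Of 26 hemogenic progenitor genes 18 were lower and 1 higher, and 20 and 1 adjusted over the list alone (median -2.09, camera adjusted p = 1e-10, estimated 0.015). In the megakaryocyte list 18 of 19 fell, and 19 adjusted over the list alone (median -3.35, camera adjusted p = 6.1e-14, estimated 0.15). In the class II list 9 of 10 fell, among them HLA-DRA (-6.85, adjusted p = 0.000252). The count was 3184 without MYB+/- replicate 1 and 2146 without MYB+/- replicate 2. The embryonic globin HBZ (4.96, adjusted p = 0.0387) and the red cell anion exchanger SLC4A1 (4.67, adjusted p = 0.0331) were called higher. Without MYB-/- replicate 3 they lay at -0.56 (adjusted p = 0.794) and -0.30 (adjusted p = 0.886), and their calls also ended without either MYB+/- replicate.

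The reporter sort at day 6 asks which cells had switched on the MYB locus, and in both modified lines YFP+ cells carried red cell, megakaryocyte and blood progenitor genes. In MYB+/- cells RUNX1 stood at 583 ± 85.4 CPM in YFP+ against 50.4 ± 24.9 CPM in YFP- cells (n = 2 each), ITGA2B at 1080 ± 442 against 25.2 ± 20.1 CPM, and HBE1 at 8310 ± 2730 against 230 ± 174 CPM. YFP- cells held the matrix gene DCN (0.954 against 146 CPM) and the liver-type gene AFP, alpha-fetoprotein (0.62 against 45 CPM). Of all genes 2739 differed in MYB+/- cells by edgeR's test, 1176 higher and 1563 lower in YFP+. RUNX1 rose by 3.53 (SE 0.64, adjusted p = 0.000452), ITGA2B by 5.42 (SE 0.86, adjusted p = 0.000103) and MYB by 3.41 (adjusted p = 0.000401). DCN fell by 7.22 (adjusted p = 4.93e-07). Of 23 erythroid genes 17 were higher, and 22 adjusted over the list alone (median 4.09, camera adjusted p = 3.5e-18, 0.029 with an estimated correlation). Of 26 hemogenic progenitor genes 13 were higher, 13 adjusted over the list alone (median 1.59, estimated 0.012). Of 19 megakaryocyte genes 12 were higher and 1 lower, 13 and 1 adjusted over the list alone (median 3.04, camera adjusted p = 6e-11, estimated 0.1). The count was 1405 without YFP+ replicate 1 and 1498 without YFP+ replicate 2, and HBE1 (5.17, adjusted p = 0.00545) lost its call without YFP- replicate 2 (adjusted p = 0.0757). In MYB-/- cells GATA1, the master regulator of red cells and platelets, stood at 281 CPM in YFP+ against 0.886 CPM in YFP- cells and rose by 8.33 (adjusted p = 2e-06). RUNX1 rose by 5.75 (adjusted p = 3.77e-06) and HBE1 by 8.67 (SE 1.4, adjusted p = 0.000111). In all 3219 genes differed, 1458 higher and 1761 lower. The erythroid list (17 of 23 higher, 20 adjusted over the list alone, median 4.49, camera adjusted p = 4e-19, estimated 0.024) and the hemogenic progenitor list (15 of 26 higher, 16 adjusted over the list alone, median 2.9, estimated 0.0015) were higher in YFP+ cells. Of 19 megakaryocyte genes 16 were higher and 1 lower, 16 and 1 adjusted over the list alone (median 3.41, camera adjusted p = 7.4e-15, estimated 0.062). The count was 2011 without YFP- replicate 1.

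MYB+/+ cells sorted on CD43 at day 6 gave a like split of blood from connective tissue genes. GATA1 stood at 176 CPM in CD43+ and 0.626 CPM in CD43- cells (n = 3 each), and SPN, which encodes the sorted marker itself, at 433 ± 54.7 against 1.75 ± 0.624 CPM. HOXA9, a gene of definitive blood and of posterior mesoderm, lay in CD43- cells (0.0275 ± 0.0239 against 6.28 ± 2.16 CPM). By edgeR's test 5183 genes differed, 2168 higher and 3015 lower in CD43+ cells. Scaling moved this split, from 41.8% higher to 28.9% with the median-ratio factors, which shift the median of all genes by -0.19. GATA1 rose by 8.12 (adjusted p = 7.88e-08) and MYB by 4.71 (adjusted p = 5.2e-07). HOXA9 fell by 7.51 (adjusted p = 8.22e-05). Of 23 erythroid genes 18 were higher, and 22 adjusted over the list alone (median 4.04, camera adjusted p = 4.6e-21, 0.019 with an estimated correlation). Of 24 mesenchyme genes 18 were lower, 19 adjusted over the list alone (median -2.09, camera adjusted p = 3.2e-16, estimated 0.016). All 10 HOXA genes were lower, 10 adjusted over the list alone (median -5.70, estimated 0.02). The count was 3316 without CD43+ replicate 2 and 8268 with the replicate block. Under the block the endothelial, pluripotency and immediate early lists passed camera (adjusted p = 0.045, 0.038 and 0.037 in place of 0.19, 0.056 and 0.075).

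At day 12 the reporter-positive cells of MYB+/- cultures carried granulocyte and mast-cell transcripts, and connective tissue genes lay higher in YFP- cells. EPX stood at 933 ± 722 CPM in YFP+ cells (n = 3), and GFI1 at 44.6 ± 15.3 against 3.3 ± 0.972 CPM in YFP- cells (n = 2). RELN, an extracellular matrix protein gene, stood at 3.74 against 34.8 CPM. ITGA2B was high in both fractions, at 2350 ± 2160 and 3300 ± 996 CPM. The fractions differed in 759 genes by edgeR's test, 280 higher and 479 lower in YFP+ cells. EPX rose by 7.13 (adjusted p = 0.000378), GFI1 by 3.75 (SE 0.5, adjusted p = 0.000378) and MYB by 4.34 (adjusted p = 0.0004). RELN fell by 3.22 (SE 0.43, adjusted p = 0.000378), and ITGA2B was not called (-0.49, adjusted p = 0.729). Of 20 granulocyte genes 12 were higher, and 19 adjusted over the list alone (median 3.73, camera adjusted p = 5.6e-17, 0.041 with an estimated correlation). Of 14 mast cell and eosinophil genes 8 were higher, 10 adjusted over the list alone (median 3.97, estimated 0.026). Of 24 mesenchyme genes 14 were lower, 18 adjusted over the list alone (median -2.27, camera adjusted p = 6e-19, estimated 0.026). Only 4 genes were called without YFP- replicate 1, which ended the calls of EPX (adjusted p = 0.0678), GFI1 (0.0672) and MYB (0.0686). The count was 394 without YFP+ replicate 2 and 1265 without YFP+ replicate 1. With the 5 libraries alone in the fit 0 genes were called.

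In MYB-/- cultures at day 12 the reporter-positive cells carried megakaryocyte genes and little of the leading granulocyte genes. ITGA2B stood at 4710 ± 865 CPM in YFP+ against 341 ± 221 CPM in YFP- cells (n = 3 each), PF4 at 4170 ± 1260 against 216 ± 128 CPM, and CSF1R at 346 ± 246 against 19.4 ± 14.7 CPM. MPO, at 2.82 ± 3.22 and 2.57 ± 2.33 CPM, and GFI1, at 0.457 ± 0.288 and 0.507 ± 0.0547 CPM, were low in both. COL3A1, a fibrillar collagen gene, stood at 199 ± 146 against 50600 ± 12500 CPM. EdgeR's test called 8257 genes, 3805 higher and 4452 lower in YFP+ cells. ITGA2B rose by 3.79 (SE 0.65, adjusted p = 4.88e-05), PF4 by 4.27 (adjusted p = 0.000103) and MYB by 5.46 (adjusted p = 1.16e-07). COL3A1 fell by 7.99 (SE 0.74, adjusted p = 1.01e-08), and GFI1 was not called (-0.12, adjusted p = 0.889). All 19 megakaryocyte genes were higher, 19 adjusted over the list alone (median 3.95, camera adjusted p = 7.1e-13, 0.16 with an estimated correlation). All 24 mesenchyme genes were lower, 24 adjusted over the list alone (median -5.28, camera adjusted p = 2.6e-27, estimated 0.0048). In MYB+/+ cells at day 12, CD43+ cells carried genes of both lineages. ELANE, neutrophil elastase, stood at 167 ± 62 against 0.481 CPM, and HDC rose by 8.59 (adjusted p = 3.07e-08). ITGA2B stood at 508 ± 280 against 14.8 ± 7.5 CPM, and KDR at 28.9 ± 9.6 against 842 ± 218 CPM (n = 3 each). There 9247 genes differed, 4358 higher and 4889 lower in CD43+ cells. ELANE was higher by 8.50 (adjusted p = 3.15e-08) and KDR lower (-4.87, SE 0.49, adjusted p = 2.83e-08). Of 20 granulocyte genes 19 were higher, 19 adjusted over the list alone (median 7.52, camera adjusted p = 1.4e-15, estimated 0.047). Of 19 megakaryocyte genes 14 were higher, 14 adjusted over the list alone (median 5.1, camera adjusted p = 8.7e-11, estimated 0.15). Of 24 endothelial genes 20 were lower with 1 higher (median -3.93, camera adjusted p = 2.1e-06, estimated 0.2).

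The interaction of genotype with fraction at day 12 tests directly whether the YFP+ to YFP- difference changes with loss of MYB. Megakaryocyte genes separated the fractions more in MYB-/- than in MYB+/- cultures, and MYB+/- YFP- cells carried them as well. Connective tissue genes shifted the other way. ITGA2B shifted by 4.28 (SE 0.88, adjusted p = 0.0013), PF4 by 5.18 (adjusted p = 0.00111), COL3A1 by -5.20 (SE 0.9, adjusted p = 0.000279) and GFI1 by -3.87 (SE 0.69, adjusted p = 0.000334). The junctional adhesion gene AMICA1 shifted by 6.67 (adjusted p = 4e-05) and FRY, a regulator of cell shape, by -7.23 (adjusted p = 2.1e-06). By edgeR's test 4088 genes had an interaction, 2074 positive and 2014 negative. Of 19 megakaryocyte genes 18 shifted up, 19 adjusted over the list alone (median 4.97, camera adjusted p = 2e-20, 0.053 with an estimated correlation). Of 24 mesenchyme genes 18 shifted down, 20 adjusted over the list alone (median -3.70, camera adjusted p = 5.9e-16, estimated 0.053). The count was 2145 without MYB+/- YFP- replicate 2. At day 6 the interaction was called for 1 gene, ST8SIA1 (-4.48, SE 0.7, adjusted p = 0.0228). It was called for 0 genes in 7 of the 8 fits that left out a library, the exception being MYB-/- YFP+ replicate 2. ST8SIA1's call also ended in 5 of 9 alternative settings (adjusted p from 0.0549 to 1). The endothelial list shifted up (median 2.23, camera adjusted p = 8.6e-29, estimated 0.029, 3 adjusted over the list alone).

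From day 6 to day 12 the MYB+/- YFP+ cells gained granulocyte and macrophage genes and lost red cell genes. MPO went from 0.362 ± 0.0544 CPM (n = 2) to 11600 ± 4860 CPM (n = 3), PPBP, a platelet chemokine gene, from 0.158 CPM to 1710 ± 816 CPM, and KLF1, the activator of red cell genes, from 339 ± 156 to 13 ± 10.5 CPM. GFI1 went from 244 ± 43.4 to 44.6 ± 15.3 CPM. The 2 days differed in 4867 genes by edgeR's test, 2406 higher and 2461 lower at day 12. MPO rose by 15 (SE 2.3, adjusted p = 3.44e-05) and PPBP by 13.3 (adjusted p = 3.16e-06), and KLF1 fell by 4.69 (SE 0.94, adjusted p = 0.000688). Of 20 granulocyte genes 19 were higher, 20 adjusted over the list alone (median 7.72, camera adjusted p = 1.7e-19, 0.11 with an estimated correlation). Of 23 macrophage genes 19 were higher, 21 adjusted over the list alone (median 4.03, estimated 0.29). Of 23 erythroid genes 15 were lower and 2 higher, 16 and 3 adjusted over the list alone (median -2.18, camera adjusted p = 8.2e-06, estimated 0.35). The count was 2330 without day 6 replicate 1.

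MYB-/- YFP+ cells over the same 6 days gained platelet genes and lost GFI1. PPBP went from 0.671 CPM (n = 2) to 5260 ± 799 CPM (n = 3), GP9, part of the platelet receptor for von Willebrand factor, from 3.06 ± 0.763 to 690 ± 231 CPM, and GFI1 from 188 ± 74.8 to 0.457 ± 0.288 CPM. Over time 5763 genes differed by edgeR's test, 2429 higher and 3334 lower at day 12. GP9 was higher by 7.82 (adjusted p = 6.46e-06), GFI1 changed by -8.63 (SE 0.55, adjusted p = 3.21e-10) and MYB by -3.41 (adjusted p = 3.84e-05). MPO was not called (4.93, SE 1.9, adjusted p = 0.0592) but was without day 12 replicate 2 (5.48, adjusted p = 0.0403) and in 4 of 9 alternative settings (adjusted p from 0.0065 to 0.0283). Of 19 megakaryocyte genes 15 were higher, 15 adjusted over the list alone (median 3.23, camera adjusted p = 3.6e-13, 0.32 with an estimated correlation). Of 20 granulocyte genes 5 were higher and 1 lower, 7 and 1 adjusted over the list alone (median 1.3, camera adjusted p = 0.036, estimated 0.58). The count was 2558 without day 6 replicate 2. In MYB+/+ CD43+ cells 7402 genes differed between the days, 3417 higher and 3985 lower at day 12. Day here goes with depth and with the counts of multi-copy genes, in which the MYB+/+ day 12 libraries stand apart, so this count describes the libraries. MPO went from 0.82 ± 0.366 to 21800 ± 5780 CPM (n = 3 each; 14.7, adjusted p = 7.46e-07) and KDR from 907 ± 143 to 28.9 ± 9.6 CPM (-4.97, SE 0.49, adjusted p = 3.38e-08). S100A8, a neutrophil calcium-binding protein gene, was at 0 at day 6 and at least 30900-fold higher at day 12. All 20 granulocyte genes were higher, 20 adjusted over the list alone (median 9.36, camera adjusted p = 2.4e-23, estimated 0.046).

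The interaction of genotype with day in YFP+ cells asks which changes over time depend on genotype, and the genes it called include granulocyte genes. GFI1 fell further in MYB-/- than in MYB+/- cells (-6.18, SE 0.68, adjusted p = 3.88e-05), with a call in all 10 fits that left out a library. AZU1 went from 3.72 ± 0.803 to 668 ± 346 CPM in MYB+/- and from 4.39 ± 3.1 to 1.75 ± 0.478 CPM in MYB-/- cells (-8.82, SE 1.1, adjusted p = 0.000451). ALAS1, the heme enzyme, went from 31.4 ± 12.2 to 512 ± 251 CPM and from 29.5 ± 5.47 to 45.3 ± 9.16 CPM (-3.41, SE 0.52, adjusted p = 0.00178), a call lost without MYB+/- day 6 replicate 2 (adjusted p = 0.0662) and with only the groups compared in the fit (adjusted p = 0.301). In edgeR's test 59 genes had an interaction, 3 positive and 56 negative. MPO was not called (-10, SE 4.1, adjusted p = 0.457), nor was MYB (-2.98, SE 0.74, adjusted p = 0.0982). DESeq2 called both (adjusted p = 0.00106 for MPO and 0.0125 for MYB), and MYB was also called with the GC slope in the model (adjusted p = 0.0426) and without MYB+/- day 12 replicate 1 (adjusted p = 0.0144). Of 20 granulocyte genes 6 had a negative interaction, 16 adjusted over the list alone (median -6.18, camera adjusted p = 3.4e-27, 0.023 with an estimated correlation). Of 19 megakaryocyte genes 0 had one, 0 adjusted over the list alone (median 1.28, camera adjusted p = 3.4e-08, estimated 0.37). With only the groups compared in the fit 3 genes were called. The count was 22 and 118 without MYB-/- day 6 replicate 2 and day 12 replicate 3 and 24 and 26 without MYB-/- day 12 replicates 1 and 2. It was 14 and 7 without MYB+/- day 6 replicates 1 and 2, and 302, 38 and 36 without MYB+/- day 12 replicates 1, 2 and 3. The simulated test of this interaction recovered 24% of 4-fold and 64% of 8-fold changes.

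Set against MYB+/+ CD43+ cells at day 12, granulocyte transcripts lay far lower in MYB-/- YFP+ cells, but genotype here goes with the sort marker, the line and any batch. These comparisons describe the libraries. GFI1 stood at 0.457 ± 0.288 CPM in MYB-/-, 44.6 ± 15.3 CPM in MYB+/- and 69 ± 20.8 CPM in MYB+/+ cells (n = 3 each), and ELANE at 1.84 ± 0.89 CPM in MYB+/- against 167 ± 62 CPM in MYB+/+ cells. TEK and KDR, the endothelial receptors, lay higher in both modified lines, although TEK lost its call for MYB+/- cells with only the groups compared in the fit (adjusted p = 0.0576). In edgeR's test 5903 genes differed between MYB-/- and MYB+/+ cells, 3552 higher and 2351 lower in MYB-/-. Log2 differences included GFI1 at -7.19 (SE 0.51, adjusted p = 2.23e-09) and ITGA2B at 3.21 (SE 0.63, adjusted p = 0.000525). Of 20 granulocyte genes 18 were lower, 19 adjusted over the list alone (median -7.15, camera adjusted p = 2.9e-24, 0.038 with an estimated correlation). Between MYB+/- and MYB+/+ cells 2084 genes differed, 1550 higher and 534 lower in MYB+/-. ELANE was lower (-6.52, SE 0.73, adjusted p = 2.6e-06), MPO was not called (-0.90, SE 1.1, adjusted p = 0.642). KDR was higher (3.23, SE 0.46, adjusted p = 5.53e-05). Of the granulocyte list 1 member was higher and 2 were lower (median -0.72, camera adjusted p = 0.0011, estimated 0.55). This second count was 1369 without MYB+/- replicate 1 and 716, 1239 and 1001 without MYB+/+ replicates 1, 2 and 3. Ribosomal protein genes with many near-identical copies stood apart in the MYB+/+ day 12 libraries, RPL7 at 4.29 ± 1.5 CPM against 1700 ± 1100 CPM in MYB+/- and RPS3A at 10.5 ± 0.778 CPM. So did MTRNR2L1, a nuclear copy of mitochondrial sequence, at 120 ± 25.8 CPM. Counts of such genes are uncertain.

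At day 6 few genes were called between the modified lines and MYB+/+ cells. Unadjusted p lay under 0.05 in edgeR's test for 2365 of 23004 genes with MYB-/- and for 788 with MYB+/- cells. HBE1, at 8310 ± 2730 CPM in MYB+/- YFP+ and 1610 ± 414 CPM in MYB+/+ CD43+ cells without overlap, was not called. Few calls thus do not show that the groups were alike. ROBO2, an axon guidance receptor gene, stood at 0.833 ± 0.43 CPM in MYB-/- YFP+ (n = 2) and 24.8 ± 5.25 CPM in MYB+/+ CD43+ cells (n = 3), and ST8SIA1 at 1.35 ± 0.765 and 30.7 ± 8.66 CPM. RASAL3, a Ras regulator gene of blood cells, stood at 16.2 ± 8.67 CPM in MYB+/- (n = 2) and 2.4 ± 0.684 CPM in MYB+/+ cells. In edgeR's test 40 genes differed between MYB-/- and MYB+/+ cells, 17 higher and 23 lower in MYB-/- (ROBO2 -4.90, SE 0.63, adjusted p = 0.000161; ST8SIA1 -4.50, SE 0.53, adjusted p = 4.3e-05). EdgeR's test called 22 between MYB+/- and MYB+/+ cells, 9 higher and 13 lower in MYB+/- (RASAL3 2.75, SE 0.53, adjusted p = 0.0269; PCDHGA10, a protocadherin whose gene shares exons with its cluster, -2.90, SE 0.54, adjusted p = 0.0226). With only the groups compared in the fit the calls of ROBO2 (adjusted p = 0.0592), ST8SIA1 (0.0708) and RASAL3 (0.0922) ended. The first count was 377 and 11 without MYB-/- replicates 1 and 2 and 19 and 23 without MYB+/+ replicates 1 and 2. The second was 4 and 10 without MYB+/- replicates 1 and 2 and 10, 8 and 10 without MYB+/+ replicates 1, 2 and 3. PCDHGA10 was called in none of these 5 fits (adjusted p up to 0.504), and RASAL3 only in the fit without MYB+/- replicate 2 (adjusted p up to 1).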

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

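The tests below were chosen after the result was seen, except the exchange of genotype labels at day 6 and the other splits of the libraries.

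Results were singled out here where an interaction test showed that an effect differs between genotypes. The genotype effect differed between fractions for 4088 genes at day 12 (2074 positive and 2014 negative) and for 1 gene at day 6, ST8SIA1 (-4.48, adjusted p = 0.0228). The change from day 6 to day 12 in YFP+ cells differed between genotypes for 59 genes, 3 positive and 56 negative. ST8SIA1 (3.73, adjusted p = 0.0119) and LDLRAD3, a regulator of receptor turnover (2.81, adjusted p = 0.0152), were positive. The granulocyte and eosinophil genes EPX (-11.4, adjusted p = 0.000661), MS4A3 (-9.76, adjusted p = 0.00289), AZU1 (-8.82, adjusted p = 0.000451), ARG1 (-7.78, adjusted p = 0.0167), LYZ (-6.65, adjusted p = 0.0425) and CEBPE (-6.37, adjusted p = 0.00583) were negative, as were LIN7A, a cell polarity gene (-6.58, adjusted p = 0.0292), and SLC47A1, a transporter gene (-6.39, adjusted p = 0.00178). Of these, AZU1 was called in each of the 10 fits that left out a library; the others lost the call in at least 1, EPX without MYB-/- day 6 replicate 2 (adjusted p = 0.0539), SLC47A1 without MYB+/- day 6 replicate 2 (0.0544), MS4A3 without either MYB+/- day 6 library, and LYZ in 8 of the 10.

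MYB+/- YFP+ day 12 replicate 1 held megakaryocyte transcripts near the MYB-/- level: ITGA2B stood at 4810 CPM against 794 and 1440 CPM in the other MYB+/- libraries, and MPO at 6070 against 14900 and 14000 CPM. An exchange of labels with MYB-/- replicate 3 is argued against, because the median granulocyte list level of the library labelled MYB-/- replicate 3 lay 5.81 log2 units below the lower of the other MYB+/- libraries. MYB-/- material mixed into the library needed similar shares from the megakaryocyte and endothelial lists (medians 0.516 and 0.492). Their difference of 0.0241 met the bound set for mixing. The bound set against it was met as well. Of the 18 endothelial genes at 10 CPM or more in every MYB-/- library, 9 lay below a share of 0.402 of their lowest MYB-/- level. That share is the lower quartile of the megakaryocyte list's shares. CDH5 stood at 8.19 CPM against at least 74.6 CPM. These 9 genes argue against material like these 3 MYB-/- libraries. The megakaryocyte list lay 1.11 log2 units above the higher and the granulocyte list 1.56 below the lower of the other libraries (-1.56), but these values restate the pattern and decide nothing, so a culture with more megakaryocyte and fewer granulocyte cells stays open. The preparation of this library, or a sort that differed, was not tested.

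At day 6 few genes were called between MYB-/- and MYB+/- cells, and the 2 replicates of each group differed crosswise, MYB-/- replicate 2 with MYB+/- replicate 1. The difference between replicates followed transcript GC content in all 4 groups, with a Spearman correlation across genes of at least 0.88, against -0.12 and 0.055 for the day 12 genotype differences, which is consistent with a GC bias of 4 libraries as the source of the split. Whether the spread from this trend hides genotype differences stays open. With the GC slope in the model 5 genes were called in YFP+ and 1 in YFP- cells, under the 50 set as the bound against it. In simulated counts that fit recovered 10% and 18% of 2-fold, 82% and 72% of 4-fold and 100% and 90% of 8-fold changes in the 2 fractions. Most differences near 2-fold and part of the larger ones would thus be missed. In YFP- cells RUNX1 (5.62-fold lower in MYB-/-) and GFI1B (9.49-fold lower) were called neither in the main fit nor with the GC slope. An exchange of genotype labels is argued against, but only weakly. The score was the mean log2 CPM of 46 genes higher minus that of 182 lower in MYB-/- cells in both day 12 fractions. All 4 MYB-/- day 6 libraries scored above both MYB+/- libraries of their fraction. Scores were 5.09 and 5.1 against 4.58 and 4.79 in YFP-, and 3.17 and 2.98 against 2.44 and 2.69 in YFP+ cells. The genotypes thus lay closer together than the fractions. Effects at day 6 that these tests missed remain an untested biological possibility.

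Blood transcripts were abundant in the MYB+/- YFP- fraction at day 12. For megakaryocyte genes carry-over of YFP+ cells is argued against. They stood at a median of 1.88 times their YFP+ level (quartiles 1.42 and 2.26) while the reporter stood at 0.0501 times. MYB stood at 0.0494 times its YFP+ level, but the sort on a reporter in the MYB locus selects for this, so blood cells with little MYB, and so little reporter, stay an open explanation without a test. The ratio was 0.0739 for granulocyte, 0.0613 for mast cell and eosinophil, 0.6 for macrophage, 1.56 for erythroid, 1.93 for endothelial and 4.75 for mesenchyme genes. Granulocyte and mast cell and eosinophil ratios lie near the reporter's 0.0501, so for these genes carry-over stays open. In the MYB-/- YFP- fraction 1 of 3 libraries, replicate 3, held the globin and red cell transcripts behind the calls of HBZ and SLC4A1.

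For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split of MYB-/- against MYB+/- YFP+ cells at day 12 called 1339 genes and the highest other split 1165, which exchanges MYB+/- replicate 1 and MYB-/- replicate 3. For MYB+/- against MYB+/+ the values were 2084 and 447. In MYB-/- fractions at day 12, MYB+/+ fractions at day 12 and day 6, MYB+/+ day 12 against day 6, and MYB-/- against MYB+/+, the real splits called 8257, 9247, 5183, 7402 and 5903 genes and the highest other split 0, so in each of the 7 comparisons 1 split, the real one, reached its count.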

How the results depend on the processing

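Chosen after the result was seen were the fits with the GC slope, without the 6 MYB+/+ day 12 libraries and with crossed replicate numbers; the others were planned. The cause of a difference between settings was not tested unless the setting itself shows it.

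The fall of MYB in MYB-/- YFP+ cells at day 12 kept its direction and its call in all 9 settings and all 6 fits that left out a library, between -2.93 and -3.56. Median-ratio size factors moved none of the 20 counts by more than 1.5 times; they shifted the median of all genes by -0.11, -0.12, -0.15 and -0.19 in the fraction comparisons of MYB+/- at day 12 and day 6, MYB-/- at day 6 and MYB+/+ at day 6. Over the named genes, settings other than leaving out a library kept 1106 values on their side of the threshold, ended 60 calls, made 25 and reversed 0; leaving out a library kept 730, ended 67, made 5 and reversed 2. These were HBZ and SLC4A1 in MYB-/- against MYB+/- YFP- cells at day 12, which ranged from -0.56 to 5.54 and from -0.30 to 5.29, with the lowest values without MYB-/- replicate 3.

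The test against a 2-fold change asks for more and lowered 18 counts, a result of its construction. They became 228 and 2483 for MYB-/- against MYB+/- at day 12 in YFP+ and YFP- cells; 90 and 1291 for the MYB+/- fractions at day 12 and day 6; 4750 and 1720 for the MYB-/- fractions; and 5370 and 2190 for the MYB+/+ fractions. The interaction with fraction gave 2301 at day 12 and 0 at day 6, the interaction with day 22, the changes over time 2124 (MYB+/-), 2356 (MYB-/-) and 4056 (MYB+/+), and the comparisons with MYB+/+ 2559 and 17 (MYB-/-) and 324 and 5 (MYB+/-) at day 12 and day 6.

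Fitting only the groups compared, which leaves fewer samples to estimate the spread, gave 143 and 0 for MYB-/- against MYB+/- YFP+ cells at day 12 and day 6, 0 and 1031 for the MYB+/- fractions, 1017 for the MYB-/- fractions at day 6, 8737 for the MYB+/+ fractions at day 6, 0 for the interaction with fraction at day 6, 1806 and 3481 for the changes over time in MYB+/- and MYB-/- cells, 3 for the interaction with day, 2 for MYB-/- against MYB+/+ at day 6 and 367 for MYB+/- against MYB+/+ at day 12. With the 19 libraries of the modified lines alone the counts were 470 and 1 for MYB-/- against MYB+/- YFP+ cells, 250 and 1666 for the MYB+/- fractions, 2711 and 0 for the interaction with fraction, 3141 and 3786 for the changes over time, and 21 for the interaction with day. Without the 6 MYB+/+ day 12 libraries 4 counts moved: 2 for MYB-/- against MYB+/- YFP- cells at day 6, 0 and 37 for the interactions with fraction at day 6 and with day, and 9 for MYB+/- against MYB+/+ at day 6. No filter on low counts gave 3 for MYB-/- against MYB+/- YFP- cells at day 6 and 62 for MYB-/- against MYB+/+ at day 6.

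The GC slope as a covariate raised 11 counts: to 3176 and 5 for MYB-/- against MYB+/- YFP+ cells at day 12 and day 6, 1 for YFP- cells at day 6, 2347 and 4932 for the MYB+/- fractions, 4911 for the MYB-/- and 7970 for the MYB+/+ fractions at day 6, 6365 and 2 for the interaction with fraction, 142 for the interaction with day and 3686 for MYB+/- against MYB+/+ at day 12. DESeq2 gave 2166 and 7 for MYB-/- against MYB+/- YFP+ cells, 16 for YFP- cells at day 6, 1489 for the MYB+/- fractions at day 12, 264 for the interaction with day, and 235 and 35 for MYB-/- and MYB+/- against MYB+/+ at day 6; for none of these was the cause tested.

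The replicate block moved 6 counts: 1 for MYB-/- against MYB+/- YFP- cells at day 6, 3095 and 5361 for the MYB+/- fractions at day 12 and day 6, 5464 for the MYB-/- and 8268 for the MYB+/+ fractions at day 6, and 0 for the interaction with fraction at day 6. Where the numbers pair the samples it changed no list call other than those named for the MYB+/+ fractions at day 6, and with the GC slope in the same fit that count was 9255. By the description's number the block gave 2023 for the MYB+/- fractions at day 12 and 6660 for the interaction with fraction. In none of the 5 other comparisons with 3 pairs did every sample correlate best with its own number. Every sample did so in the MYB+/+ fractions at day 6. In the MYB-/- fractions at day 12, YFP- replicate 1 correlated at 0.33 with YFP+ replicate 2 and at 0.18 with its own number. At day 6 the fractions of the modified lines hold 2 pairs each, too few to take as pairing, with same-number correlations of 0.91 in MYB+/- and 0.92 in MYB-/- cells. The deviations of MYB-/- and MYB+/- day 6 libraries with the same number had correlations of -0.93 and -0.92; with crossed numbers the counts were 3 in YFP+ and 1 in YFP- cells over all libraries, and 709 and 1545 in fits of the 4 libraries alone, which leave 1 residual degree of freedom and use a pairing chosen from the data.

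Leaving out each library in turn gave 407 to 2592 and 0 to 2 genes for MYB-/- against MYB+/- YFP+ cells at day 12 and day 6, and 2146 to 4535 and 0 to 1 for YFP- cells. The fractions gave 4 to 1265 and 1405 to 1989 in MYB+/-, 6578 to 7963 and 2011 to 2488 in MYB-/-, and 7737 to 7988 and 3316 to 4221 in MYB+/+ cells. The interaction with fraction gave 2145 to 4766 and 0 to 1, the interaction with day 7 to 302, and the changes over time 2330 to 4978 (MYB+/-), 2558 to 6323 (MYB-/-) and 5625 to 6250 (MYB+/+). Against MYB+/+, the ranges were 4041 to 5664 and 11 to 377 for MYB-/- and 716 to 2797 and 4 to 10 for MYB+/-. Of 540 list tests, camera called 260 with the preset correlation and 50 with the estimated one, 268 with the block and 263 with median-ratio factors. Depth limits the MYB+/+ day 12 libraries most, where a floor of 3 counts over a group stands at 0.116 CPM for CD43+ and 0.111 CPM for CD43- cells.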

Other observations

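The test of the reporter's level was chosen after the result was seen. Venus transcripts in YFP+ cells stood at 3.41 times the MYB+/- level in MYB-/- cells at day 6 and at 0.622 times at day 12, with neither difference called. That 2 cassette copies against 1 set the level is a candidate explanation that predicts a ratio between 1.5 and 3 at both days; neither day lies in that range, but the libraries of the genotypes overlap at day 12, so the copies stay undecided.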
